A study of Mus musculus with 10 samples.

How the data were processed

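Forebrain was dissected from mouse pups on postnatal day 0, and total RNA from each of 10 animals was labelled for a mouse exon array, per the labels' protocols. The labels place 5 animals in a wild-type group and 5 in an Elavl3/Elavl4 double knockout group, all on a mixed background of C57BL/6 and CD-1. Each sample is a separate animal with its own number. The series is described as littermate pairs, and no label states which animals are littermates, so the groups were compared without pairs. Replicate numbers used here follow the order of deposit and only name a sample.

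The deposited values are log2 expression values, normalized and summarised by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA subtracts background, brings the arrays to a common distribution and combines the probes of a probe set into 1 value. The versions, the annotation set and the level of summary are not given in the sources used here. The notes name the mouse build mm8. Values had been rounded before deposit, which limits small differences. The table held 65529 probe sets, and no column belonged to another sample. The identifiers had 9 gaps of over 1000, and whatever falls there is not analysed here. Elavl1, Gap43 and Mapt are not analysed here.

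Gene symbols came from the platform annotation and were updated through gene identifiers against the RefSeq gene table of GRCm38.p6. That assembly differs from mm8. It served for names, for the chromosome of a gene, for which genes neighbour each other and for distances from Elavl3 and Elavl4. Of the probe sets, 15419 carried 1 symbol, 961 carried several and 49149 carried none. Those with 1 symbol named 13534 genes, and 15071 of these probe sets matched the gene table. Probe sets with several symbols named no gene. For 310 probe sets with 1 symbol, the gene lay on another chromosome than its neighbours in identifier order, where neighbours were the 20 nearest named probe sets on each side; such names are stated as uncertain where printed.

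Groups were compared on the deposited log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term and no filter. Adjusted p-values are Benjamini-Hochberg values over all 65529 probe sets, two-sided, with a threshold of 0.05. Values of single genes also received a two-sided exact permutation test over the 252 ordered splits of 10 arrays into 5 and 5, in which the smallest possible p is 0.00794. A total of 37 gene lists were fixed before the data were examined. Of these, 35 were tested with limma's camera at its preset correlation of 0.01 between genes, on the brightest single-symbol probe set of each gene, with adjustment over the 35 lists; lists with fewer than 3 measured genes would have been left out. The ELAV-like family and the sex-linked genes were described and not tested. Each list's members were also adjusted over the list alone, from the p-values of the fit over all probe sets. Genes within 10 Mb of Elavl3 or Elavl4 were compared with all others by a two-sided Fisher exact test.

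Named genes follow a rule fixed in advance. It takes the 12 largest rises and the 12 largest falls past the threshold among single-symbol probe sets whose groups do not overlap, leaving out predicted, olfactory receptor, microRNA, small nucleolar, LOC and Rik symbols and the sex-linked genes. It then takes the ELAV-like family and from each list up to 4 members past the threshold, or the 2 with the smallest p where fewer than 2 passed. Other genes and unnamed probe sets were picked after their values were seen, as stated beside them.

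The tests were tested on simulated data. Values for all 65529 probe sets were drawn from the means and spreads of the real arrays, and 200 probe sets were changed by known folds. The comparison of double knockout with wild-type recovered 14% of the 50 changes of 1.5-fold, 56% of 2-fold, 96% of 4-fold and 98% of 8-fold, with 10 false calls. The changed probe sets were drawn at random from all 65529, of which 49149 carry no symbol, and those vary more than named ones. The rates therefore describe all probe sets together and not the named genes. In a second simulation, with 1 list shifted by 0.4 log2, camera called that list and 0 others. Genes were drawn independently in both, so the 0 says nothing about false lists among correlated genes, and in the real arrays 84 of 99 other splits called 1 list or more.

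Alternatives planned before the data were examined were quantile normalization, median centring, cyclic loess, a filter on dim probe sets, single-symbol probe sets only, eBayes with trend and robust settings, array weights, Xist as a covariate, pairs by nearest animal number as a block, and leaving out each array in turn. For the counts of probe sets they were a threshold of 0.01, a size of at least 1.5-fold, an unmoderated unequal-variance test and the removal of genes beside the targeted loci. For lists they were camera with an estimated correlation, fry, the mean of all probe sets of a gene, and genes unique to 1 list. Alternatives added after seeing the data were an exact permutation test of list means and the removal of probe sets whose names were out of place. No depth applies to arrays, and the number of arrays limits the precision: the median SE over 13534 genes was 0.117 log2. Figures were drawn with matplotlib 3.10.9.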

Results

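Expression was measured with exon arrays in the forebrain of newborn mice, in 5 wild-type animals and 5 animals lacking both Elavl3 and Elavl4, which encode RNA-binding proteins of neurons. Log2 values ran from 1.94 to 13.03, and array medians from 5.05 to 5.24. Among all arrays but wild-type replicate 4, pairs of arrays correlated at 0.958 or more over probe sets. Wild-type replicate 4 correlated with the others at 0.933 to 0.946. No probe set had a duplicate profile.

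The targeted genes were examined first, in every sample. Elavl3 was 11.11 ± 0.34 (SD, n = 5) in wild-type and 6.03 ± 0.54 (SD, n = 5) in double knockout forebrain. The difference was -5.08 log2 (SE 0.256, 95% interval -5.65 to -4.52), a 33.9-fold lower level in the double knockout, with limma's adjusted p = 3.15e-05. Elavl4 was 7.58 ± 0.13 in wild-type and 6.26 ± 0.25 in double knockout (SD, n = 5 each), a difference of -1.32 (SE 0.134, 95% interval -1.62 to -1.02), or 2.50-fold lower, with adjusted p = 0.0130. For both genes all 5 double knockout values lay below all 5 wild-type values, and the exact permutation p was 0.00794, the smallest this design can give. Elavl3 reached 10.52 to 11.39 in wild-type animals and 5.53 to 6.94 in double knockout animals, and Elavl4 7.42 to 7.69 and 5.88 to 6.49. Which exons each value averages is not stated.

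**Figure D1:**
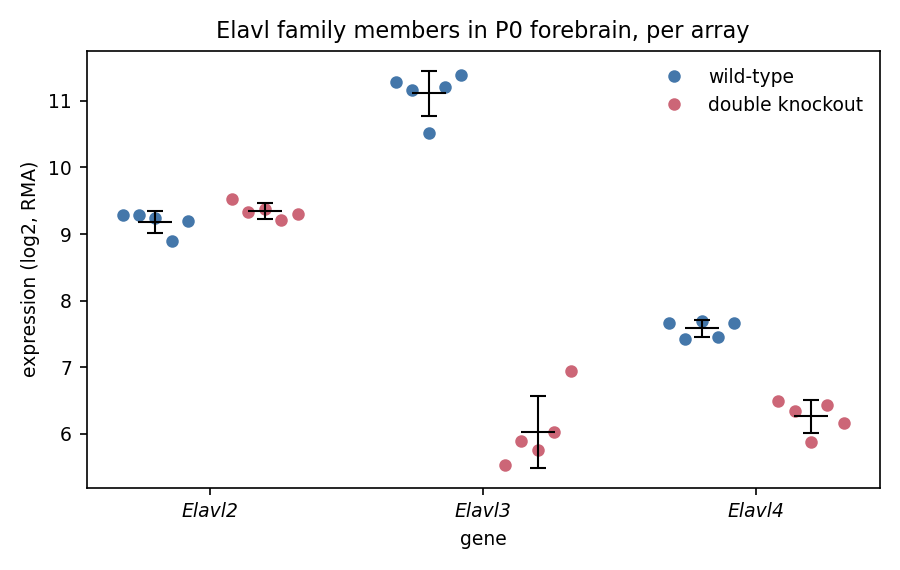
Expression of Elavl2, Elavl3 and Elavl4 in log2 units, with each point 1 array, a bar at the group mean and whiskers of 1 SD, for 5 wild-type and 5 double knockout arrays. Elavl3 lies at 10.52 or more in every wild-type array and at 6.94 or less in every double knockout array.

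Elavl2, a family member that was not targeted, was 9.18 ± 0.17 in wild-type and 9.35 ± 0.11 in double knockout (SD, n = 5 each). Its difference of 0.17 (95% interval -0.08 to 0.41) did not pass, with limma's adjusted p = 0.858, and was 0.09 without wild-type replicate 4. Elavl1 is not analysed here. The call for Elavl4 was lost without wild-type replicate 1, 2, 4 or 5 or double knockout replicate 1, 4 or 5, with adjusted p from 0.0275 to 0.0761 over the 10 omissions and a difference between -1.38 and -1.22. It was also lost with Xist as a covariate (adjusted p = 0.0522) and with pairs by nearest animal number as a block. The unmoderated unequal-variance test lost it too and called only Elavl3.

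Across the array, the loss of both genes was accompanied by few differences that passed the test. No probe set was higher in the double knockout and 5 were lower in limma's test over 65529 probe sets. The 5 were Elavl3, Elavl4 and 3 probe sets without a gene symbol. At an unadjusted p under 0.05 there were 4040 probe sets, 2295 higher and 1745 lower, against 3276 expected by chance. The unmoderated unequal-variance test called 0 higher and 1 lower. For 13396 of 13534 genes (99.0%) the 95% interval of the difference lay within 2-fold, and for 12323 (91.1%) within 1.5-fold. Leaving out single arrays gave 1 lower probe set without wild-type replicate 1, 2, 4 or 5 or double knockout replicate 1, 4 or 5, and between 4 and 6 otherwise.

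Named probe sets varied less than unnamed ones. The median residual SD was 0.164 over probe sets with 1 symbol and 0.333 over those with none, and limma's shared prior drew on both. In the fit over all probe sets 425 of the 15419 single-symbol probe sets had an unadjusted p under 0.05. That is fewer than the 771 expected by chance, so that fit was conservative for named genes. Of the 49149 probe sets without a symbol, 3594 had such a p, a share above the 0.05 expected by chance. The excess of small p-values over all probe sets thus lay among unnamed ones. Whether the shared prior was too lenient for them was not tested. The unmoderated unequal-variance test, which uses no shared prior, kept only Elavl3 and none of the unnamed calls. Fitted by themselves, the single-symbol probe sets gave 894 with such a p, of which 284 were higher and 610 lower. There 1 probe set passed the threshold as higher, and Elavl3 and Elavl4 passed as lower. The higher one was C530025M11Rik, an uncharacterised gene picked after its values were seen, at 6.98 in wild-type and 7.51 in double knockout (difference 0.53, SE 0.0682, adjusted p = 0.0400 there and 0.490 over all probe sets). Its other probe set differed by -0.09 (adjusted p = 0.940 in the single-symbol fit). The fit of single-symbol probe sets in their place in identifier order could not test either, since the gene table gives this gene no position.

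The 3 unnamed probe sets lay side by side in a run of 6 that had lower values in the double knockout, by -1.18 to -4.32 log2. In identifier order the run lies between Prkcsh and Cnn1. In the gene table of GRCm38.p6 Elavl3 lies between these genes, and so do Zfp653 and Ecsit, whose own probe sets, picked after their values were seen, were at 0.12 and 0.17 without a call. The probe sets named Elavl3 (6993854), Zfp653 (6993857) and Ecsit (6993859) all lie in another part of the identifier order than the run. Whether the run belongs to any of these genes, and which strand it reads, is not known here. The mean of the run was 7.45 ± 0.79 in wild-type and 4.88 ± 0.12 in double knockout (SD, n = 5 each), with an exact permutation p of 0.00794, and was picked after the values were seen. Probe set 6987426 had the greatest difference of the run, -4.32, and 6987425 was at -3.02, both with limma's adjusted p = 0.0121. None of the 3 unnamed calls was kept without wild-type replicate 1, 2, 4 or 5 or double knockout replicate 1, 4 or 5, and 1 of the 3 was lost without double knockout replicate 3. The 20 measured genes beside Elavl3 had a median difference of -0.06 and a range of -0.21 to 0.24, and 0 of them passed.

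**Figure D2:**
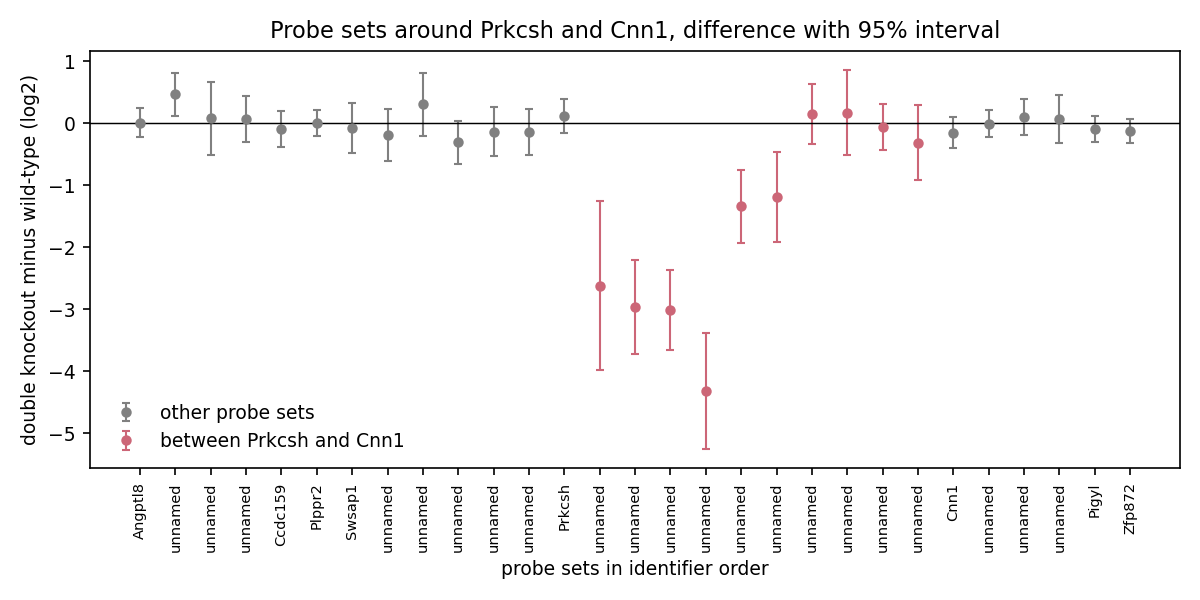
Difference between double knockout and wild-type (log2, points) with its 95% interval (whiskers) for probe sets in identifier order around Prkcsh and Cnn1, over 5 arrays per group. The 6 probe sets after Prkcsh lie between -4.32 and -1.18, and the others shown lie between -0.31 and 0.47.

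Genes within 10 Mb of Elavl3 or Elavl4 were compared with all other genes, since a mixed background can leave donor sequence beside a targeted allele. Only probe sets with 1 symbol and a position in the gene table entered. The unnamed run between Prkcsh and Cnn1, with its 3 calls, was therefore left out, and the comparison says nothing about it. Among 308 probe sets near the loci 0 passed, and among 14761 elsewhere 0 passed, the targeted genes left out, so Fisher's exact test could not separate them (p = 1). An unadjusted p under 0.05 was found for 2.92% near the loci and 2.70% elsewhere (Fisher's exact p = 0.723).

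Immediate early genes, which neurons switch on within minutes of activity, stood lower in the double knockout as a list. Of 15 measured members 14 had values below 0, with a median of -0.196 log2, and limma's camera gave an adjusted p of 0.00336. With an estimated correlation of 0.321 between the members the call was lost, with adjusted p = 0.920, and it was lost without wild-type replicate 5, with a median of -0.101 and adjusted p = 0.192. No member passed the test, over all probe sets or adjusted over the list alone. Nr4a1, a nuclear receptor, was 7.06 ± 0.29 in wild-type and 6.73 ± 0.08 in double knockout (difference -0.33), and Junb, a subunit of the AP-1 transcription factor, differed by -0.36, and by -0.23 without wild-type replicate 4. The list's mean score was highest in wild-type replicates 5 and 4, at 0.348 and 0.177, against -0.042 to -0.004 in the other wild-type arrays and -0.187 to -0.023 in the double knockout. Without replicate 4 the list still passed, with a median of -0.17 and adjusted p = 0.00712. The mean over the list had an exact permutation p of 0.0238, not adjusted over the lists. A median below 0 was found in 26 of the 35 lists tested, and camera called 1 of the 35. With an estimated correlation it called 0, and so did limma's fry, by direction and in either direction.

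**Figure D3:**
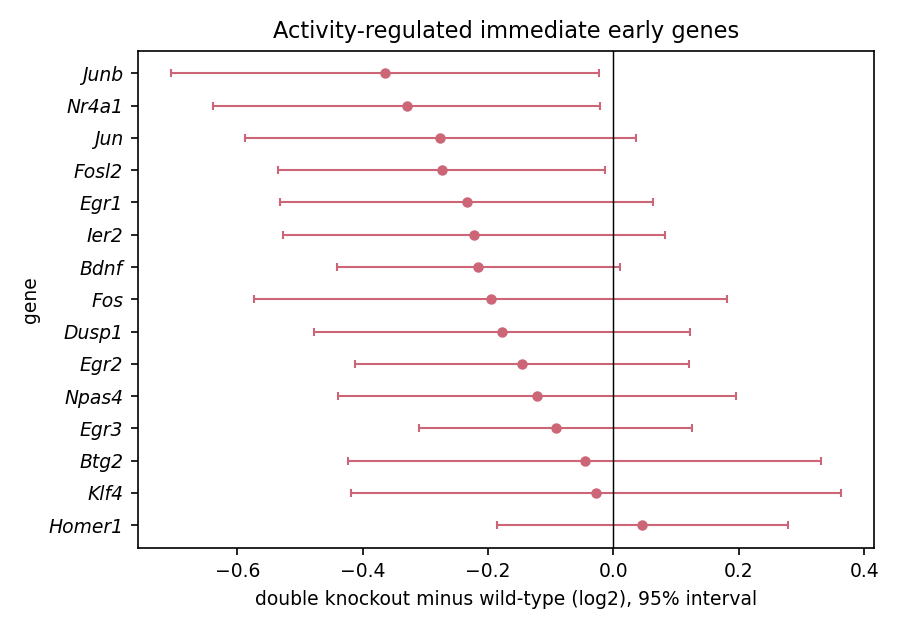
Difference between double knockout and wild-type (log2, points) with 95% interval (whiskers) for each immediate early gene, over 5 arrays per group. Of 15 genes, 14 lie below 0, and none passed the test over all probe sets.

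None of the 417 measured members of the 35 lists passed, over all probe sets or adjusted over the list alone. Both adjustments used p-values of the fit over all probe sets, which was conservative for named genes. The share of all named genes below 0 is not given here, so counts of members above or below 0 have no baseline. Values of members named below are given without any call, and leaving out 1 array moved the difference of 39 of all 72 named genes by over 1.5 times. The adjusted p values printed for lists are those of camera at its preset correlation unless stated. Camera sets a list against the other genes and not against 0. Its p therefore does not test the median or the counts printed beside it. Over other splits of the 10 arrays that test called a median of 3 lists, so a list that passed without 1 array is no evidence of a shift by itself. With an estimated correlation the lowest adjusted p was 0.920.

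Among lists of transmission and excitability, presynaptic vesicle and release genes had 11 of 14 values below 0 and a median of -0.105 (adjusted p = 0.179). Rims1, a scaffold of the release site, was at -0.20, and Nrxn3, a presynaptic adhesion molecule, at 0.24. Without wild-type replicate 4 the list passed with a median of -0.13 (adjusted p = 0.0271). Postsynaptic density genes had 7 of 13 above 0 and a median of 0.03 (adjusted p = 0.496), with Lrrtm2 at -0.23 and the kinase Camk2a at 0.19. Glutamate receptors had 6 of 11 above 0 (median 0.03, adjusted p = 0.5004), with Grm5 at 0.37, and GABA receptors 2 of 6 above 0 (median -0.085, adjusted p = 0.764), with Gabrb1 at -0.25. Glutamate synthesis and transport genes had 7 of 8 below 0 (median -0.05, adjusted p = 0.764). In it the vesicular glutamate transporters Slc17a6 and Slc17a7 lay at 0.20 and -0.19, moving to 0.12 without wild-type replicate 4 and to -0.09 without wild-type replicate 3. Voltage-gated ion channels had 12 of 23 below 0 (median -0.004, adjusted p = 0.419), with Cacna2d1 at 0.44 and the sodium channel Scn1a at 0.24.

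Genes of axons and neuronal identity gave no call either. Axon growth and cytoskeleton genes had 16 of 24 below 0 (median -0.03, adjusted p = 0.764), among them Stmn4 at -0.27 and the neurofilament gene Nefl at -0.24. Axon guidance genes had 13 of 16 above 0 (median 0.06, adjusted p = 0.173), with the netrin receptor Dcc at 0.24, and passed without wild-type replicate 1 (median 0.08, adjusted p = 0.0284) or wild-type replicate 2 (median 0.07, adjusted p = 0.0474). GABA neuron genes had 8 of 13 above 0 (median 0.06, adjusted p = 0.179), with the transcription factor Dlx6 at 0.28, and passed without wild-type replicate 4 (median 0.10, adjusted p = 0.00712). Medians were 0.03 in deep cortical layer neurons (8 of 13 above 0, adjusted p = 0.230), -0.06 in upper layer neurons (3 of 11 above 0, adjusted p = 0.764), -0.07 in striatal neurons (4 of 10 above 0, adjusted p = 0.621), -0.08 in hippocampal neurons (2 of 6 above 0, adjusted p = 0.764), -0.05 in Cajal-Retzius cells (2 of 8 above 0, adjusted p = 0.791) and -0.07 in thalamus and hypothalamus (3 of 15 above 0, adjusted p = 0.822). Examples were the striatal dopamine receptor Drd2 at 0.25, the neuropeptide Cck at -0.25 and the granule cell factor Prox1 at 0.35.

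Among progenitors and cell division, radial glia genes had 7 of 13 above 0 (median 0.01, adjusted p = 0.496), with Gli3 at 0.17 and Hes5 at -0.12. Intermediate progenitor and newborn neuron genes had 4 of 8 above 0 (median -0.01, adjusted p = 0.764), with Neurod1 at 0.13, which was -0.004 without double knockout replicate 4. Cell cycle genes had 8 of 17 above 0 (median -0.004, adjusted p = 0.419), with Pcna at -0.19.

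Glial and other cell types were also without a call. Astrocyte genes had 10 of 11 below 0 (median -0.09, adjusted p = 0.179), with Fgfr3 at -0.19 and Agt at -0.25, and passed without wild-type replicate 4 (median -0.16, adjusted p = 0.00712). Meningeal and fibroblast genes had 9 of 11 below 0 (median -0.07, adjusted p = 0.179), with Foxc1 at -0.22, and passed without wild-type replicate 4 (median -0.13, adjusted p = 0.00712). Medians were -0.065 in the oligodendrocyte lineage (6 of 8 below 0, adjusted p = 0.565), -0.04 in microglia and macrophages (10 of 15 below 0, adjusted p = 0.764), -0.01 in endothelial cells and pericytes (7 of 13 below 0, adjusted p = 0.764), -0.04 in red blood cells (3 of 4 below 0, adjusted p = 0.799) and -0.11 in choroid plexus and ependyma (6 of 8 below 0, adjusted p = 0.822). Scores of the choroid plexus list ranged from -0.72 to 0.57 between arrays, wider than those of any other tested list.

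Lists related to RNA-binding proteins had values on both sides of 0. Neuronal RNA-binding and splicing regulators had 13 of 23 above 0 (median 0.03, adjusted p = 0.230), with the splicing factors Nova1 at 0.31 and Celf6 at -0.23. Transcripts reported to be bound by neuronal ELAV-like proteins had 5 of 12 above 0, a median of -0.04 and a mean of 0.03 (adjusted p = 0.615). In that list Nova1 was at 0.31 and the neurotrophin Bdnf at -0.22. Gap43 and Mapt are not analysed here.

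Stress and housekeeping lists were likewise without a call. Interferon response genes had 10 of 10 below 0 (median -0.10, adjusted p = 0.179), with Ifit1 at -0.25, and passed without wild-type replicate 4 (median -0.11, adjusted p = 0.0459). Cholesterol synthesis genes had 10 of 12 below 0 (median -0.14, adjusted p = 0.190), with Mvd at -0.43, and passed without double knockout replicate 1 (median -0.19, adjusted p = 0.00206). Medians were -0.06 for the hypoxia response (8 of 11 below 0, adjusted p = 0.885), -0.08 for ATF4 and the unfolded protein response (8 of 11 below 0, adjusted p = 0.5004), -0.09 for the p53 response and apoptosis (9 of 12 below 0, adjusted p = 0.419), 0.02 for cytosolic ribosomal proteins (6 of 10 above 0, adjusted p = 0.595) and 0.03 for the mitochondrial respiratory chain (11 of 17 above 0, adjusted p = 0.179). Ldha, at -0.51 in the hypoxia list and at -0.09 without wild-type replicate 4, Fdps and Rpl7 carry names that are out of place in identifier order and stay uncertain. In 6 of the 35 lists the median and the direction of camera differed in sign: ion channels, newborn neurons, cell cycle, striatal neurons, microglia and reported ELAV targets.

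**Figure D4:**
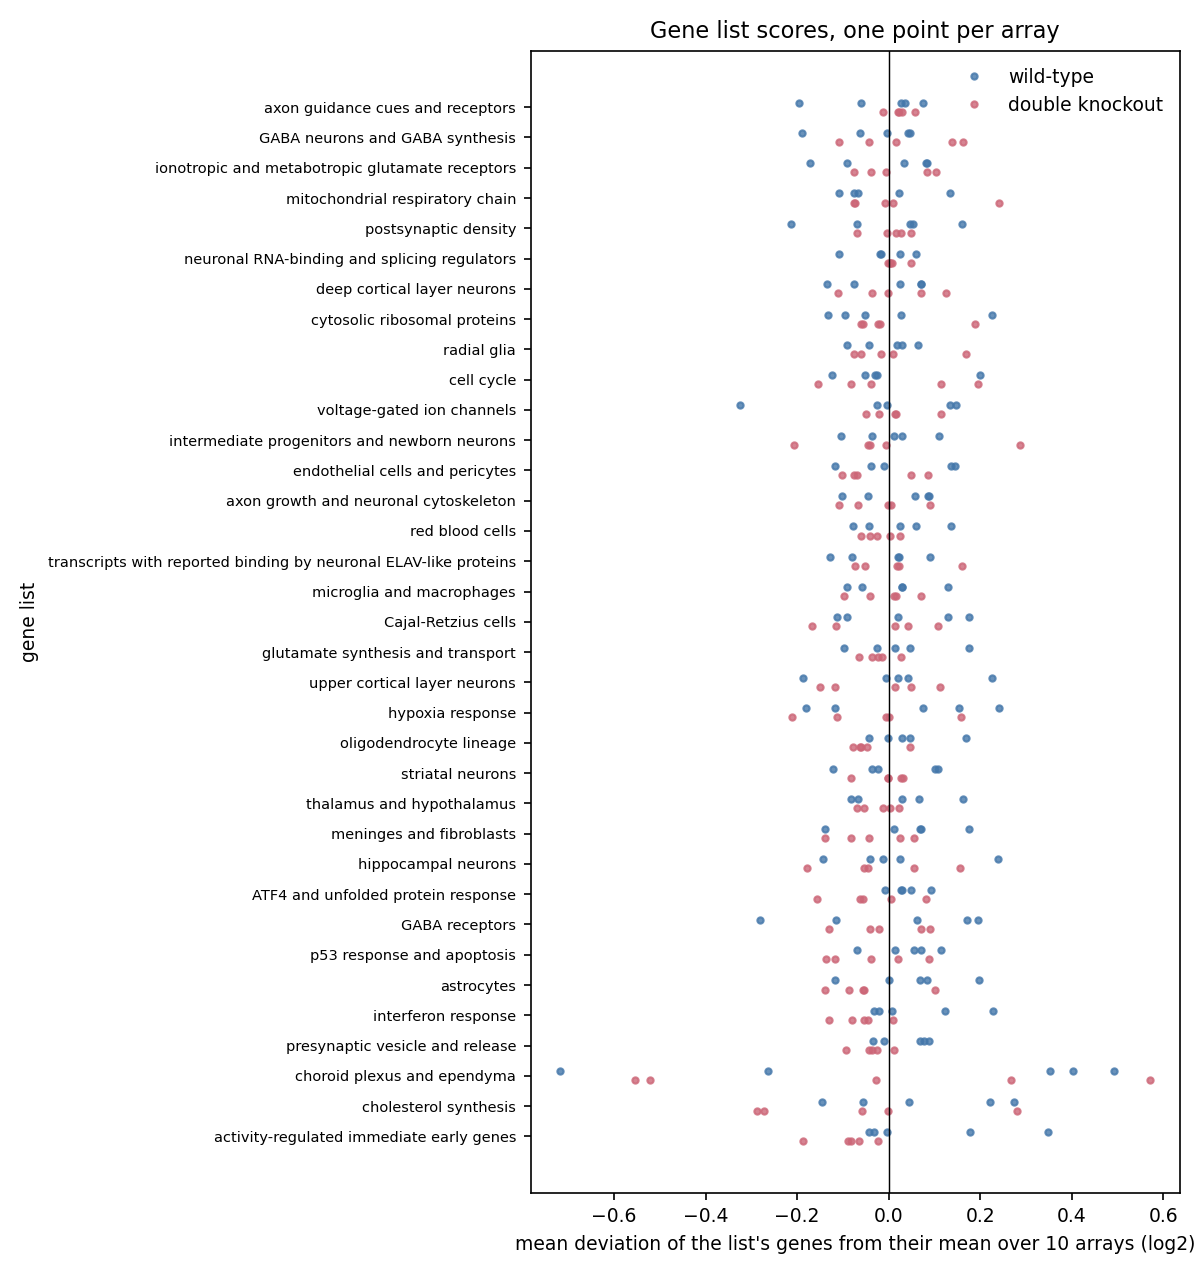
Mean deviation of each list's genes from their mean over the 10 arrays (log2), 1 point per array, for 5 wild-type and 5 double knockout arrays and 35 lists. Points of both groups overlap in every list, and choroid plexus and ependyma has the widest range, -0.72 to 0.57.

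Sex-linked genes were described and not tested as a list. Xist, fixed in advance as a covariate, was 7.58 ± 3.71 in wild-type and 5.92 ± 3.24 in double knockout (SD, n = 5 each), and Kdm5d and Eif2s3y differed by 0.89 and 1.15, each without a call. The names of both are out of place in identifier order. Both were low in wild-type replicates 2 and 3 and double knockout replicate 1, Kdm5d at 4.42 to 4.62 and Eif2s3y at 4.06 to 4.28. In all other arrays they were at 7.45 to 8.16 and 8.45 to 9.19. This shared pattern argues against genes that are not sex-linked, and which sex-linked gene each reads stays uncertain. Within each group these values varied more between animals than they differed between groups.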

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

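The tests of the 6 unnamed probe sets, of the immediate early genes, of a wrong label and of other splits for calls and lists were chosen after their results were seen. The test of the signal range of wild-type replicate 4 was written before. A total of 226 groups of 5 values were examined for 1 value far from the other 4, by its gap to the nearest over the group's range. In 19 of them a value stood apart, where chance alone gives about 11.3, 1 group in 20.

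The first pattern is a run of 6 unnamed probe sets between Prkcsh and Cnn1 in identifier order, with wild-type replicate 3 apart: its mean of the 6 was 6.08, against 7.54 to 7.96 in the other wild-type arrays and 4.78 to 5.08 in the double knockout, and its Elavl3 value was 10.52, against 11.16 to 11.39. A fall of the whole region is argued against by the genes beside Elavl3, whose median was -0.063 with 0 of 20 past the threshold. Deviations of the run and of Elavl3 from their group means correlated over 10 arrays (Pearson r = 0.541, exact permutation p = 0.0435; Spearman rho = 0.745, p = 0.0344; the only such relation computed). Without the 2 arrays farthest from the median, wild-type replicate 3 and double knockout replicate 5, r was 0.802. Without wild-type replicate 3 alone it was 0.270 (rho = 0.65), and 0.189 with group means taken again without that array. Without double knockout replicate 5 alone, which goes against the relation, r was 0.817, and 0.893 with group means taken again. The size of r thus depends on these 2 arrays, and whether the run follows the level of Elavl3 stays open. The RNA the run reads, an altered Elavl3 allele in wild-type replicate 3 and strain differences under the probes stay open and untested, and so does the knockout itself as the cause, a hypothesis found on the same data.

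The second pattern is wild-type replicate 4, whose mean correlation with the other arrays was 0.938, against 0.959 to 0.965 in the other wild-type arrays. It deviated from its group by 0.15 in probe sets under 5 and by -0.16 in those over 8, which might reflect a compressed signal range, but after cyclic loess its deviation still had an SD of 0.523, against 0.422 in the next array, so the range is not the whole cause. Its Elavl3 value of 11.21 lies above every double knockout value (highest 6.94), which excludes a double knockout sample under a wild-type label. A difference in dissection, RNA quality or the animal itself was not tested. No biological explanation was tested, since the array belongs to 1 group.

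The third pattern is the lower level of immediate early genes. Variation between animals shared by these genes is consistent with the data: with the estimated correlation of 0.321 the adjusted p was 0.920. The call also depends on wild-type replicate 5, since without it the adjusted p was 0.192, although the median stayed below 0 at -0.101. Sex of the pups is argued against by the median, which was -0.20 with Xist as a covariate and -0.196 without. The adjusted p with the covariate was 0.00128, from camera at its preset correlation. That p adds little, since the same test called lists in most other splits. An effect of the knockout stays open as untested beyond the chance of the grouping. Of 100 splits of the arrays (of 126 possible), 85 gave at least as many lists as the 1 of the real split, up to 11. The median of the other splits was 3 lists, more than the real split gave, so chance cannot be excluded. Splits with many lists could come from a structure of the samples, correlated genes or 1 deviant array, which was not tested.

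For the 5 probe sets past the threshold, 1 of 100 splits, the real one, gave as many, and the highest other gave 1. The 5 are the targeted genes and 3 unnamed probe sets, and in each the groups do not overlap. Every other split mixes the groups and widens their spread, so it could hardly call them. The result was thus nearly set by the calls themselves, and no conclusion on chance is drawn from it.

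Other values stood apart from their group. In wild-type replicate 4 these were Elavl2 at 8.89 (others 9.20 to 9.29), Slc17a6 at 7.37 (7.72 to 7.82), Grm5 at 5.89 (6.38 to 6.57), Ldha at 9.50 (7.13 to 7.74) and Fdps at 4.68 (3.85 to 4.06). In double knockout replicate 4 Slc12a2 was at 9.46 (8.94 to 9.06) and Cck at 8.55 (7.98 to 8.14), and the scores of the oligodendrocyte list at 0.0456, of cytosolic ribosomal proteins at 0.1885 and of the mitochondrial respiratory chain at 0.240 lay above the others. Col3a1 in wild-type replicate 5 was at 8.03 (7.91 to 7.94), and Ldha in double knockout replicate 3 at 7.09 (7.34 to 7.39). In double knockout replicate 5 the score of neuronal RNA-binding regulators was 0.0484. In double knockout replicate 1 Kdm5d was at 4.62 (others 7.84 to 8.16), Eif2s3y at 4.11 (8.95 to 9.19) and the score of the sex-linked list at -0.866. Wild-type replicates 2 and 3 were as low, with Kdm5d at 4.42 and 4.62 and Eif2s3y at 4.06 and 4.28. The names Kdm5d, Eif2s3y, Ldha and Fdps are out of place in identifier order. Ldha and Fdps stay uncertain, and so does which sex-linked gene Kdm5d and Eif2s3y each read.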

How the results depend on the processing

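The exact permutation of list means and the removal of names out of place were chosen after seeing the data. Elavl3 stayed lower and past the threshold under all 19 alternatives, from -5.31 to -4.96 over the omissions of single arrays and from -5.20 to -5.07 over the other 9. For the count of probe sets, 1 was higher with single-symbol probe sets only. In a test chosen after seeing the data, adjusting the p-values of the fit over all probe sets over these alone gave it an adjusted p of 0.547 and 0 higher, so fewer tests are not the cause and the prior of limma is. The count of lower probe sets, 5, was 2 with a replicate block (Elavl3 and 6987426), 2 with single-symbol probe sets only, 2 with names in place, 3 with Xist as a covariate, 1 at a threshold of 0.01 and 1 with the unmoderated test, Elavl3 in both, and 1 to 6 over the omissions. Single-symbol settings leave out the 3 unnamed probe sets by construction; for the block, Xist and the unmoderated test the cause was not tested, and omissions leave fewer arrays. Elavl4 was -1.32 with the block (adjusted p = 0.0982) and -1.30 with Xist (adjusted p = 0.0522), no longer past the threshold, and between -1.38 and -1.22 over the omissions, with adjusted p from 0.00154 to 0.0982 over all others; the cause was not tested. Lists shifted numbered 4 with array weights, which add GABA neurons, astrocytes and meninges, 0 with an estimated correlation, 0 with fry and 0 to 6 over the omissions. Exact permutation gave 0, which was nearly set by the design: 1 list at the smallest p of 0.00794 has an adjusted p of 0.278 over 35 lists, and at least 6 lists must pass together. The immediate early list's median of -0.196 lost its call with the estimated correlation, where correlation of 0.321 in place of 0.01 is the cause, and with fry, which asks another question; its loss with exact permutation shows nothing for the reason above. Over the omissions it ran from -0.2325 to -0.101. For genes near the targeted loci Fisher's exact p stayed at 1, which shows nothing with 0 calls. Of 1326 values of 70 other named genes, 1325 kept their direction and their side of the threshold and 1 turned sign without a call. Of 850 values of 34 other lists, 791 did so, 11 gained a call and 48 turned sign without one. The series is described as littermate pairs, which the labels do not identify. Deviations of pairs by nearest animal number correlated at -0.0006 to 0.156, only 2 of 5 over 0.1, and 6 of 10 arrays correlated best with their own partner, a hint from the data. The highest correlation of a wild-type and a double knockout array that are not partners was 0.215, above every pair, so the pairing stays unsettled. Dim probe sets limit small differences, and a filter on them left the count at 5.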

Other observations

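The test of small p-values over other splits was written before its result was seen. Among single-symbol probe sets fitted by themselves, 894 had an unadjusted p under 0.05, against 771 expected, and 610 of them were lower in the double knockout. A hypothesis is that many genes shift slightly with the loss of Elavl3 and Elavl4. It was not borne out: 24 of 100 splits of the 10 arrays gave as many, with 2537 in the highest other, so chance cannot be excluded. Splits with far more could come from a structure of the samples, correlated genes or 1 deviant array, which was not tested.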
